A study of Homo sapiens with 12 samples.

How the data were processed

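Total RNA from Daudi cells was prepared with RNeasy columns, turned into biotin-labelled cRNA with the CodeLink Expression Assay Kit and hybridized to single-channel CodeLink arrays, per the labels' protocols. There are 12 arrays in 4 groups of 3, namely untreated cells, cells kept in AICAR, cells stimulated with anti-CD40 and IL-4, and cells given AICAR and then stimulated. Whether AICAR stayed on the cells during stimulation is not given in the sources used here. The deposited table holds 1 linear intensity per probe and array, with column means between 0.990 and 1.01, from which it was read that the authors had scaled each array to a mean of about 1. The scanner, the software and the methods of background subtraction and scaling are not given in the sources used here, and the table has no detection flags or negative controls.

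The table has 54840 probes. Between 314 and 1116 values per array were missing, most on AICAR replicate 2, and between 126 and 1187 were at or below 0. The array medians ran from 0.0946 to 0.164. Correlations between arrays lay between 0.891 and 0.976, with a mean of 0.94 within and 0.932 between groups. Gene symbols came from the array's annotation table and were matched to current symbols by gene identifier, so that 23472 probes had 1 symbol, 905 had several and 30463 had none. Probes with several or no symbols were tested but not named.

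A pseudocount of 0.0129, the median of all values (0.129) divided by 10, was added, sums at or below 0 were set to the pseudocount, and log2 was taken. Because the array medians differed by more than 10%, the values were quantile normalized, by a rule fixed before the data were examined. Probes were kept if their mean intensity lay above the 30th percentile (0.0681) and each group had at least 2 values, which left 38326 and set aside 16514. Each probe was fitted in limma 3.58.1 (R 4.3.3) with 4 group means, 8 residual degrees of freedom and empirical Bayes moderation with a variance trend. The contrasts were stimulated against untreated, AICAR against untreated, AICAR then stimulated against stimulated, AICAR then stimulated against AICAR, and the interaction. P-values were adjusted by the Benjamini-Hochberg method within each contrast, with a threshold of 0.05, and adjusted p-values of single genes are from limma. Intensities are deposited values, given as mean ± SD, and log2 changes are given with their standard errors.

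Gene lists, 32 in number and written before the data were examined, were tested with limma's camera at a preset inter-gene correlation of 0.01 over 13418 genes with complete values, taking the brightest probe of each gene and adjusting over the lists of a contrast. The same test with a correlation estimated from the data is given beside it wherever the call changed. Counts adjusted over the list alone apply the Benjamini-Hochberg method to the members only. Genes were named by a rule with 3 parts, also written before the data were examined. Provisional symbols count in its first part but may go unprinted, members from its second part need not all be printed, and each gene stands by its brightest tested probe. These were the 10 largest rises and the 10 largest falls of each contrast among genes past the threshold whose groups did not overlap (5 and 5 for AICAR then stimulated against AICAR and for the interaction), up to 4 members past the threshold with the largest change in each list, and 26 index genes, some of which are not reported here.

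Whether the replicate numbers pair the samples was checked before the fits were compared. After group means were removed, the 18 pairs of arrays with the same number had correlations between 0.132 and 0.497 (mean 0.302), the 36 pairs with different numbers had a mean of -0.15 and a highest value of -0.0267, and all 12 arrays were closest to their own number. Because deviations cancel within a group, a positive same-number mean makes the different-number mean negative, so the latter is not separate evidence. The exact p over 216 assignments of the numbers was 0.00463. By the rule fixed beforehand the numbers pair the samples, and since the labels give only the numbers, the fit without a block is the one reported and values with the number as a block (6 residual degrees of freedom) stand beside it where a call or count changes. Fits not named as blocked, those with an array left out among them, keep the variation between replicate numbers in their error.

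The code was tested on simulated data with the 38326 probes and known changes. Changes of 4-fold were recovered in 72.9% to 77.1% and changes of 8-fold in 85.7% to 93.4% of cases in the 4 pairwise contrasts, and changes of 2-fold in 12.7% to 18.3%. False calls made up 2.34% to 7.63% of calls, and a list shifted by 0.5 was found at adjusted p = 1.26e-09 with 0 other lists called. The simulated noise was independent between probes and arrays, so this cannot show how the list test behaves when members are correlated. The alternatives were larger and smaller pseudocounts, median centring, cyclic loess, no filter, a filter at the 50th percentile, a minimum change of 2-fold, only the groups compared, no variance trend, the replicate block, the estimated correlation, the mean of all probes of a gene, and each of the 12 arrays left out. The deposited scaling, the estimated correlation with the block, the holding out of all arrays of a replicate number and the average AICAR effect were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.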

Results

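Gene expression was measured in Daudi cells, an established B cell line derived from a Burkitt lymphoma, on 12 single-channel CodeLink arrays, 3 for each of 4 groups. The first group was untreated. The second was kept in 2.5 mM AICAR for 7 h, and the third was stimulated for 6 h with anti-CD40 at 1 µg/mL together with IL-4 at 10 ng/mL. The fourth was given 2.5 mM AICAR for 1 h and then stimulated in the same way for 6 h. Whether AICAR stayed on the cells during those 6 h is not given in the sources used here. If it was removed, the 2 groups given AICAR differ in length of exposure as well as in stimulation. AICAR is a nucleoside that cells convert to an AMP analogue, which activates AMP-activated protein kinase. Anti-CD40 and IL-4 stand in for signals that a B cell receives from helper T cells. The series title speaks of anti-CD40 and/or IL-4, but the labels of every stimulated array name both. The arrays gave between 53724 and 54526 values each for 54840 probes, and 38326 probes were bright and complete enough to test. Of these, 17777 carried 1 gene symbol and stood for 14425 genes. The number of arrays limits the precision of all values, and because the labels do not say whether replicates were separate cultures, the p-values measure only the spread between these samples.

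Stimulation alone raised a small set of genes steeply. The chemokine CCL17, which attracts T cells through the receptor CCR4, rose 94.9-fold, from a deposited intensity of 0.158 ± 0.042 to 15.2 ± 6.13 (mean ± SD, n = 3 and 3, probe 227078; log2 change 6.57 ± 0.31 SE, limma adjusted p = 1.04e-06). CXCL10, a chemokine induced by interferons, rose 36.4-fold, from 0.778 ± 0.361 to 25.1 ± 6.49 (probe 142109; log2 change 5.18 ± 0.35, adjusted p = 2.2e-05). EBI3, a subunit of heterodimeric cytokines, rose from 0.151 ± 0.0363 to 4.47 ± 2.08, a log2 change of 4.77 ± 0.33 (adjusted p = 2.2e-05). The death receptor FAS rose by 3.88 ± 0.23 (adjusted p = 9.2e-06). The activation marker CD83 rose by 3.48 ± 0.35 (adjusted p = 0.000833) and TRAF1, an adaptor of TNF receptors, by 3.42 ± 0.28 on the log2 scale (adjusted p = 0.00012). Of the 38326 probes tested, 50 rose and 1 fell, for 38 and 1 genes. With the replicate number as a block, 152 rose and 14 fell, and these included all 51 of the first count.

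The CD40 and NF-kB target genes moved most as a list. Of 35 tested, 8 rose and 0 fell (13 rose with the block, and 18 rose when adjusted over the list alone). Their median log2 change was 0.738 and the list test gave adjusted p = 2.33e-42 (adjusted p = 0.0027 with an estimated correlation). NFKBIA, the inhibitor that NF-kB induces against itself, rose from 1.1 ± 0.174 to 7.55 ± 0.174 (log2 change 2.88 ± 0.19, adjusted p = 2.2e-05). BCL2A1, an anti-apoptotic BCL2 relative, rose by 3.12 ± 0.37 (adjusted p = 0.00332). TNFAIP3, a deubiquitinase that restrains NF-kB, rose by 1.87 ± 0.27 (adjusted p = 0.0153). CD40 itself had a log2 change of 2.27 ± 0.43 (adjusted p = 0.106, 0.000446 with the block and 0.0488 in the fit of 1 value per gene). Of these 35 genes, 19 also stand in other lists.

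Of 24 IL-4 and STAT6 target genes, 2 rose and 0 fell (7 with the block, 7 adjusted over the list alone). Their median was 0.228 and the list test gave adjusted p = 2.88e-07 (adjusted p = 0.126 with an estimated correlation). FCER2, the low-affinity IgE receptor CD23, had a log2 change of 1.28 ± 0.40 (adjusted p = 1, 0.00391 with the block). SOCS1, a feedback inhibitor of cytokine signalling, had 1.19 ± 0.23 (adjusted p = 0.0912, 0.0317 with the block). CCL22, CISH and IL4R had log2 changes of -0.04, 0.03 and -0.41, none past the threshold. Among 37 cytokines, chemokines and receptors, 4 rose and 0 fell (6 with the block, 7 adjusted over the list alone). Their median was only 0.0323, or 0.0662 under median centring, while their mean was 0.672, since CCL17, CXCL10, CXCL11 and CCL3 carried the list (adjusted p = 2.88e-07, and adjusted p = 0.126 with an estimated correlation). CXCL11 rose by 3.45 ± 0.34 (adjusted p = 0.000733) and CCL3 by 3.18 ± 0.45 (adjusted p = 0.0133).

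Antigen presentation and co-stimulation genes rose as a list, with 3 of 27 higher, namely CD83, CD80 and CD58, and 0 lower (9 higher with the block, 10 adjusted over the list alone). Their median was 0.374 and the list test gave adjusted p = 3.33e-15 (adjusted p = 0.126 with an estimated correlation). CD58, a ligand for CD2 on T cells, rose by 1.59 ± 0.20 (adjusted p = 0.00693) and the co-stimulator CD80 by 1.72 ± 0.28 (adjusted p = 0.0367). Interferon-stimulated genes also rose as a list, with 3 of 32 higher and 0 lower (8 with the block, 10 adjusted over the list alone). Their median was 0.653, at adjusted p = 5.42e-22 (adjusted p = 0.0455 with an estimated correlation, and adjusted p = 0.0721 with an estimated correlation and the block). The RNA sensor RIGI rose by 2.25 ± 0.30 (adjusted p = 0.00912), the GTPase GBP1 by 2.21 ± 0.29 (adjusted p = 0.00722) and the RNA sensor IFIH1 by 1.67 ± 0.27 (adjusted p = 0.0334). Of 32 immediate early genes, 2 rose, the kinase SGK1 (2.99 ± 0.23, adjusted p = 6.99e-05) and the phosphatase DUSP5 (2.63 ± 0.43, adjusted p = 0.032), and 0 fell (4 with the block, 4 adjusted over the list alone). Their median was 0.14, at adjusted p = 1.27e-05 (adjusted p = 0.0166 with an estimated correlation).

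Another 4 lists passed narrowly, each at adjusted p = 0.0481. The 28 endoplasmic reticulum chaperone genes were higher with a median of 0.162 and the 29 apoptosis regulators with a median of 0.141. The 19 germinal centre genes were lower, with a median of -0.228, and the 28 histone genes with a median of -0.0988. With an estimated correlation these gave adjusted p = 0.865, adjusted p = 0.467, adjusted p = 0.442 and adjusted p = 0.865. The apoptosis list gave 0.0554 with the block and 0.0509 under cyclic loess. The germinal centre call ended under median centring (0.208), cyclic loess (0.0509) and the deposited scaling (0.0731) and with no filter (0.0541). The chaperone and histone calls ended with no filter (0.0541 and 0.0754), a filter at the 50th percentile (0.0865 and 0.0531) and the larger pseudocount (0.0503 and 0.053, with a histone median of -0.0643). The members of the 4 lists past the threshold were FAS and BCL2A1 in the apoptosis list (2 higher and 1 lower adjusted over the list alone) and LMO2 in the germinal centre list (1 higher adjusted over the list alone). LMO2, a transcription factor, rose by 1.92 ± 0.28 (adjusted p = 0.0146) against the direction of its list. The other lists had 0 (0 adjusted over the list alone). Each of these 4 calls ended without single arrays, with adjusted p = 0.709 for the chaperones and 0.171 for the apoptosis list without untreated replicate 1. The germinal centre list gave 0.184 and the histones 0.25 without stimulated replicate 1, where the histone median was 0.0518. The remaining 22 lists did not pass (adjusted p from 0.0508 to 0.965), although G1 regulators were lower with the block (median -0.106, adjusted p = 0.0508, 0.0266 with the block, and adjusted p = 0.506 with an estimated correlation and the block). With the block 2 class switching, 2 plasma cell and 1 B cell identity genes rose and 1 T and NK cell marker fell, in lists without a member past the threshold otherwise. With 1 array left out, the median of antigen presentation genes was lowest at 0.155 without untreated replicate 1. That of IL-4 and STAT6 target genes ran from 0.133 without stimulated replicate 2 to 0.358 without stimulated replicate 1, and that of the apoptosis list was lowest at 0.0304 without stimulated replicate 2. The chaperone median was 0.0319 without untreated replicate 1 and 0.34 without stimulated replicate 1. The germinal centre median was -0.346 and the cytokine median 0.0717 without stimulated replicate 3, where that of immediate early genes was 0.233. ICAM1, BCL6, CDKN1A, CCND2, HMGCS1, FASN, TXNIP and DDIT4 were named in advance and had log2 changes of 0.48, -0.54, 0.43, -0.31, 0.76, 0.19, -0.70 and -0.13, none past the threshold.

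Of 21 named genes past the threshold, 11 kept their call in every fit that left out 1 array. KIF26B, a kinesin family member that rose by 3.51 ± 0.50 (adjusted p = 0.0146), was weakest without untreated replicate 1 (adjusted p = 0.095). Without stimulated replicate 3 the calls ended for CCL3 (0.0815), DUSP5 (0.233), CD80 (0.28), LMO2 (0.115), RIGI (0.0705), GBP1 (0.0616), IFIH1 (0.233) and TNFAIP3 (0.132). So did that of DDX11-AS1, an antisense transcript and the only probe that fell (-1.15 ± 0.18, adjusted p = 0.0258, and 0.221 without that array).

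**Figure D1:**
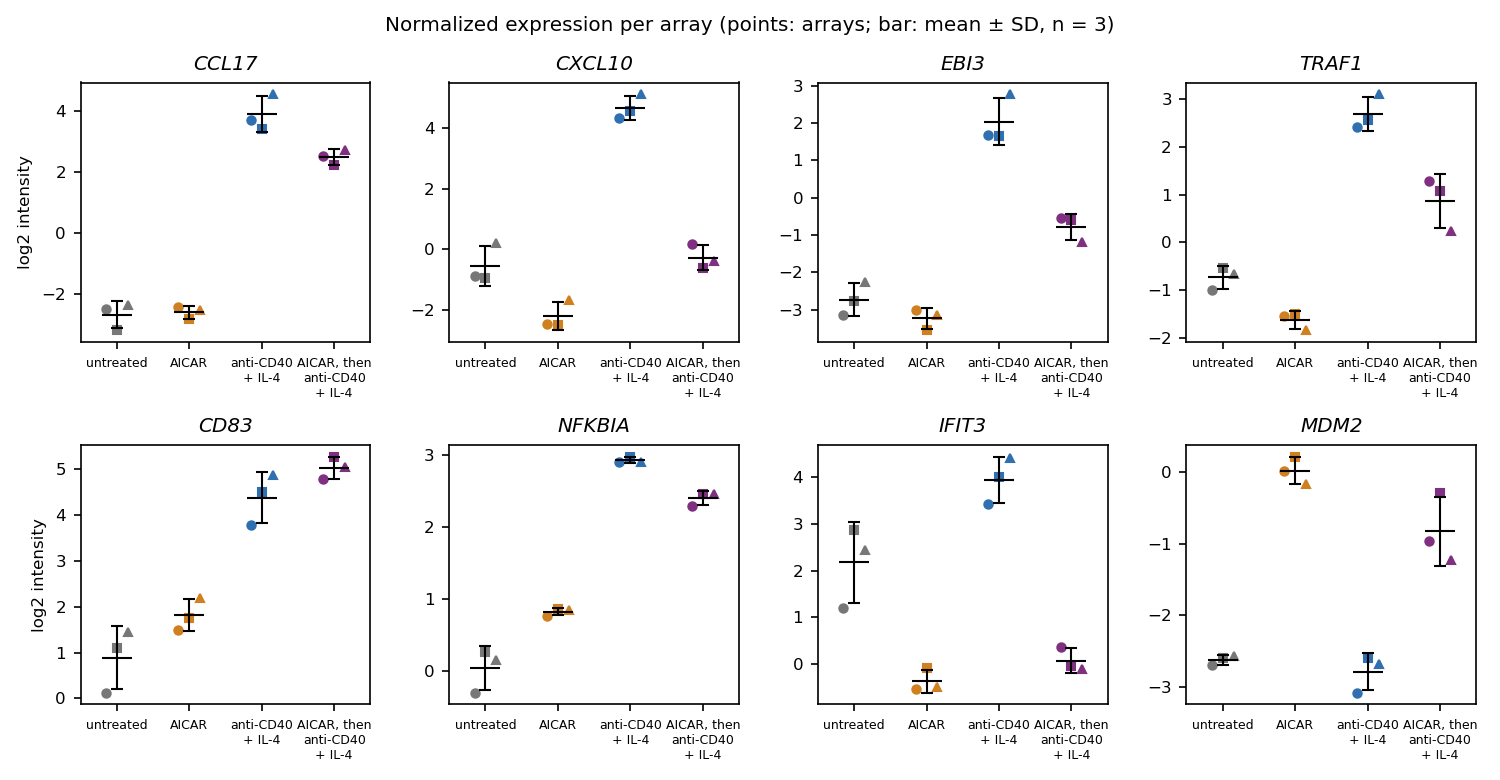
Normalized log2 intensity of 8 genes on each of the 12 arrays, by group; circles, squares and triangles are replicates 1, 2 and 3, and black bars show mean ± SD (n = 3). CCL17, CXCL10 and EBI3 were higher after stimulation (log2 changes 6.57, 5.18 and 4.77), IFIT3 was lower with AICAR (-2.55 and -3.88) and MDM2 was higher (2.63 and 1.95).

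AICAR alone changed many more genes than stimulation did, and most of those with a name were lower. Interferon-stimulated genes were prominent among them. IFIT3 fell from 5.02 ± 2.46 to 0.736 ± 0.155 (mean ± SD, n = 3 and 3; log2 change -2.55 ± 0.38 SE, adjusted p = 0.00263). MX2, a restriction factor of viruses, fell by 2.33 ± 0.32 (adjusted p = 0.00166), and SAMD9L, an interferon-induced growth regulator, fell by 2.49 ± 0.38 (adjusted p = 0.00302). MDM2, the ubiquitin ligase of p53 and a p53 target itself, rose from 0.162 ± 0.0138 to 0.963 ± 0.155 (log2 change 2.63 ± 0.23, adjusted p = 0.000121). SPIB, an Ets factor of B cells, fell from 16.7 ± 3.64 to 4.28 ± 1.06 (log2 change -1.96 ± 0.26, adjusted p = 0.00114). Of 38326 probes, 482 rose and 869 fell, for 268 and 623 genes, so that 35.7% of the 1351 were higher. With the replicate block 3459 passed (1438 higher and 2021 lower), among them all 1351. Only 744 passed under median centring and 24.3% of 1472 were higher under the deposited scaling.

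GPX1, a glutathione peroxidase, rose from 0.0686 ± 0.0492, close to the filter value of 0.0681, to 0.962 ± 0.492 (log2 change 3.86 ± 0.54, adjusted p = 0.0017). The size of its rise therefore rests on a dim probe, with 3.35 without untreated replicate 3. HDAC6, a tubulin deacetylase, rose by 3.78 ± 0.46 (adjusted p = 0.000776) on its brightest probe, and its other probe had the opposite sign. RBBP6, a ubiquitin ligase that binds p53 and RB1, rose by 2.82 ± 0.22 (adjusted p = 7.44e-05), and BCL10, an adaptor towards NF-kB, by 2.79 ± 0.26 (adjusted p = 0.000188). NFYA, a CCAAT-binding factor, rose by 2.65 ± 0.33 (adjusted p = 0.000887) and CCDC88C by 2.36 ± 0.38 (adjusted p = 0.0043). DIDO1 rose by 2.68 ± 0.34 (adjusted p = 0.000921), with 1 of 3 other probes opposite in sign. Genes outside the lists that fell included CCDC71L (-3.03 ± 0.21, adjusted p = 7.44e-05), KRCC1 (-2.80 ± 0.44, adjusted p = 0.00377), and RNF4BP (-2.76 ± 0.24, adjusted p = 0.000121). Others were PPP1R10, a regulatory subunit of a protein phosphatase (-2.76 ± 0.20, adjusted p = 7.44e-05), GNB1L (-2.63 ± 0.28, adjusted p = 0.000425) and the protease TYSND1 (-2.48 ± 0.27, adjusted p = 0.000425).

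Of 32 interferon-stimulated genes, 10 fell and 0 rose (17 fell with the block, 13 adjusted over the list alone). Their median log2 change was -0.904 and the list test gave adjusted p = 4.47e-08. The call was lost at the correlation estimated for these genes, 0.255 (adjusted p = 0.722 with an estimated correlation). Of 27 p53 target genes, 7 rose and 0 fell (14 with the block, 12 adjusted over the list alone). Their median was 0.88, or 0.455 without untreated replicate 1, at adjusted p = 4.47e-08 (adjusted p = 0.722 with an estimated correlation). Besides MDM2, the death receptor TNFRSF10A rose by 2.19 ± 0.38 (adjusted p = 0.00673), and ZMAT3, an RNA-binding protein, by 1.95 ± 0.22 (adjusted p = 0.000581). BBC3, the pro-apoptotic PUMA, rose by 1.87 ± 0.37 (adjusted p = 0.0135), whereas CDKN1A had a log2 change of 0.21 ± 0.21 (adjusted p = 0.811). BCL2L11, the pro-apoptotic BIM, rose by 1.45 ± 0.24 (adjusted p = 0.00515) in the list of apoptosis regulators. Of these 29 genes 2 rose and 1 fell (6 and 1 with the block, 4 and 1 adjusted over the list alone), and the list did not pass (adjusted p = 0.307).

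Histone genes were higher as a list, with a median of 0.416 and adjusted p = 0.0016 (adjusted p = 0.791 with an estimated correlation). Of 28 tested, 2 rose and 0 fell (7 and 1 with the block, 10 and 1 adjusted over the list alone). AICAR replicate 1 had a mean of the list at 0.039 over the untreated mean, against 0.938 and 0.846 in replicates 2 and 3. Untreated replicate 1 was also the lowest of its group, at -0.207 against 0.131 and 0.076. Over all groups the list was higher in replicates 2 and 3 than in replicate 1, by medians of 0.517 and 0.503. Part of the gap therefore goes with the replicate number. Without AICAR replicate 1 the median was 0.697. Replication-dependent H3C14, a histone gene outside that list, rose by 2.46 ± 0.40 (adjusted p = 0.00462) and H2BC8 by 2.76 ± 0.53 (adjusted p = 0.0121). The 41 oxidative phosphorylation subunits were higher as a list by a median of 0.193 (adjusted p = 0.00253, and adjusted p = 0.791 with an estimated correlation) with 0 members past the threshold (3 with the block, 0 adjusted over the list alone). Class switching and somatic hypermutation genes were lower as a list, with 3 of 25 lower and 0 higher (9 with the block, 8 adjusted over the list alone). Their median was -0.352, at adjusted p = 0.0312 (adjusted p = 0.791 with an estimated correlation). The members were RAD50 (-1.56 ± 0.28, adjusted p = 0.00859), MRE11 (-1.14 ± 0.21, adjusted p = 0.0106) and NBN (-0.99 ± 0.22, adjusted p = 0.0263), which together form a complex that senses DNA breaks. That list call ended without untreated replicate 2 (adjusted p = 0.122) and without AICAR replicate 3 (0.113). Both it (0.0682) and the histone call (0.118, median 0.213) ended with a filter at the 50th percentile.

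Of 31 genes of B cell identity and B cell receptor signalling, 3 fell and 0 rose (7 lower and 1 higher with the block, 5 lower adjusted over the list alone), and the list passed with the block (adjusted p = 0.08, 0.036 with the block, and adjusted p = 0.685 with an estimated correlation and the block). Besides SPIB these were PTPN6, the phosphatase SHP-1 (-1.29 ± 0.23, adjusted p = 0.00773), and EBF1, a factor that commits cells to the B lineage (-0.84 ± 0.19, adjusted p = 0.0251), of whose other probes 1 of 2 had the opposite sign. Among 35 CD40 and NF-kB target genes, 1 rose and 2 fell (3 and 3 with the block, 2 and 4 adjusted over the list alone; list adjusted p = 0.857), and NFKBIA rose by 0.78 ± 0.19 (adjusted p = 0.0409). Among 24 IL-4 and STAT6 target genes, 3 fell and 0 rose (3 lower and 1 higher with the block, and the same adjusted over the list alone; list adjusted p = 0.942). They included STAT6 itself, the transcription factor that IL-4 activates (-1.42 ± 0.29, adjusted p = 0.0178), and SOCS1 (-1.04 ± 0.23, adjusted p = 0.0243). Of 37 cytokines and chemokines, 3 fell and 0 rose (3 lower and 1 higher with the block, 3 lower adjusted over the list alone; list adjusted p = 0.933), and CXCL10 fell by 1.65 ± 0.35 (adjusted p = 0.0223). CD58 fell by 1.26 ± 0.20 (adjusted p = 0.00444) and CD70, a ligand of the TNF family, rose by 1.23 ± 0.19 (adjusted p = 0.00383) among the 27 antigen presentation genes (1 and 1, or 4 higher and 6 lower with the block, and 2 and 4 adjusted over the list alone; list adjusted p = 0.933).

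The other metabolic lists did not pass. Of 23 fatty acid oxidation and PPAR genes, 1 fell and 0 rose (1 higher and 2 lower with the block, 1 lower adjusted over the list alone; list adjusted p = 0.466), namely CPT1B, the muscle form of a mitochondrial fatty acid importer (-1.74 ± 0.23, adjusted p = 0.00114). Of 30 glycolysis and hypoxia genes, TXNIP, an inhibitor of thioredoxin and of glucose uptake, rose by 1.08 ± 0.18 (adjusted p = 0.006) and 1 fell (1 and 4 with the block, 1 and 2 adjusted over the list alone; list adjusted p = 0.857). Of 30 purine metabolism genes, 1 rose and 2 fell (2 and 5 with the block, 1 and 5 adjusted over the list alone; list adjusted p = 0.818). Of 35 AMPK, mTOR and autophagy genes, 1 rose and 2 fell (5 and 4 with the block, 4 and 2 adjusted over the list alone; list adjusted p = 0.942). Of 20 cholesterol synthesis and 21 fatty acid synthesis genes, 0 passed (1 higher and 2 lower, and 1 higher, with the block; 0 adjusted over the list alone), with adjusted p = 0.251 for each list, and HMGCS1 and FASN had log2 changes of 0.74 and -0.26. Of 18 oxidative stress genes, GPX1 alone rose (2 with the block, 2 adjusted over the list alone; list adjusted p = 0.268). Of 41 ribosome biogenesis and MYC target genes, 2 fell and 0 rose (3 higher and 4 lower with the block, 1 and 2 adjusted over the list alone; list adjusted p = 0.857), with TBL3 at -1.41 ± 0.22 (adjusted p = 0.00374). Of 50 ribosomal protein genes, 1 rose and 0 fell (1 adjusted over the list alone), and the list passed with the block (median 0.0938, adjusted p = 0.0827, 0.0243 with the block, and adjusted p = 0.62 with an estimated correlation and the block). That median was 0.192 under median centring, 0.054 under cyclic loess and 0.18 under the deposited scaling.

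Cell cycle lists held single genes with clear changes. Of 40 DNA replication genes, 2 fell and 0 rose (4 higher and 5 lower with the block, 1 and 4 adjusted over the list alone; list adjusted p = 0.818), with POLA2, a subunit of DNA polymerase alpha, at -2.16 ± 0.27 (n = 2 for AICAR, adjusted p = 0.0011). Of 38 mitosis genes, 1 rose and 3 fell (2 and 11 with the block, 1 and 6 adjusted over the list alone; list adjusted p = 0.0752), with HMMR, a spindle protein, at -1.56 ± 0.21 (adjusted p = 0.00131) and the separase ESPL1 at -1.54 ± 0.28 (adjusted p = 0.00828). CDKN2D, an inhibitor of cyclin D kinases, rose by 1.00 ± 0.16 (adjusted p = 0.00437) as the only called gene of 27 G1 regulators (4 and 3 with the block, 2 higher adjusted over the list alone; list adjusted p = 0.251). KLF6, an immediate early factor, rose by 1.91 ± 0.28 (adjusted p = 0.00232), the only one of its 32-gene list (2 with the block, 2 adjusted over the list alone; list adjusted p = 0.268). Germinal centre genes (1 higher, 1 lower of 19; 1 and 8 with the block, 1 and 5 adjusted over the list alone; list adjusted p = 0.268) and plasma cell genes (1 lower of 21; 3 with the block, 1 adjusted over the list alone; 0.875) did not pass. Neither did ATF4 and amino acid response genes (1 higher of 34; 4 higher and 3 lower with the block, 1 adjusted over the list alone; 0.857) and endoplasmic reticulum chaperones (1 higher of 28; 3 higher and 1 lower with the block, 2 and 1 adjusted over the list alone; 0.795). Of 23 heat shock genes 0 passed (4 lower with the block, 0 adjusted over the list alone; list adjusted p = 0.394). The lists of T and NK cell, monocyte and granulocyte, and epithelial and fibroblast markers had 0 members past the threshold (1 T and NK cell marker was lower with the block, 0 adjusted over the list alone) and gave adjusted p = 0.942, 0.857 and 0.251.

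Of the index genes named in advance, CD83 had a log2 change of 0.92 ± 0.35 that passed only with the block (adjusted p = 0.244, 0.00769 with the block). FCER2, CCL22, CCL17, CISH, IL4R, TNFAIP3, TRAF1 and CD40 had log2 changes of -0.11, 0.15, 0.09, -0.18, 0.47, 0.13, -0.89 and -0.13, none past the threshold. Likewise ICAM1, BCL6, CCND2 and DDIT4 had -0.12, -0.54, -0.42 and -0.03. BIRC3, MYC and PRKAA1 had no probe with their name, and the probes of PPARGC1A and CPT1A were too dim to test. Of 67 named genes past the threshold, 35 kept their call in every fit that left out 1 array. The calls of H2BC8 and BBC3 ended without AICAR replicate 2 (0.0573 and 0.0629). So did that of IFIT1 (-2.44 ± 0.49, n = 2 for AICAR, adjusted p = 0.0183, and 0.17 without it), where 1 AICAR value was left. That of CEP19 (-2.59 ± 0.56, adjusted p = 0.0241) ended without AICAR replicate 1 (0.081) and that of EBF1 without AICAR replicate 2 (0.103). The calls of MRE11 (0.0575), NBN (0.12), STAT6 (0.0927) and SOCS1 (0.111) ended without untreated replicate 2, that of CXCL10 without untreated replicate 3 (0.0991) and that of NFKBIA without untreated replicate 1 (0.138) and under each of the 3 other scalings. Without untreated replicate 3, untreated replicate 2 and AICAR replicate 2 the count of probes was 647, 671 and 790.

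**Figure D2:**
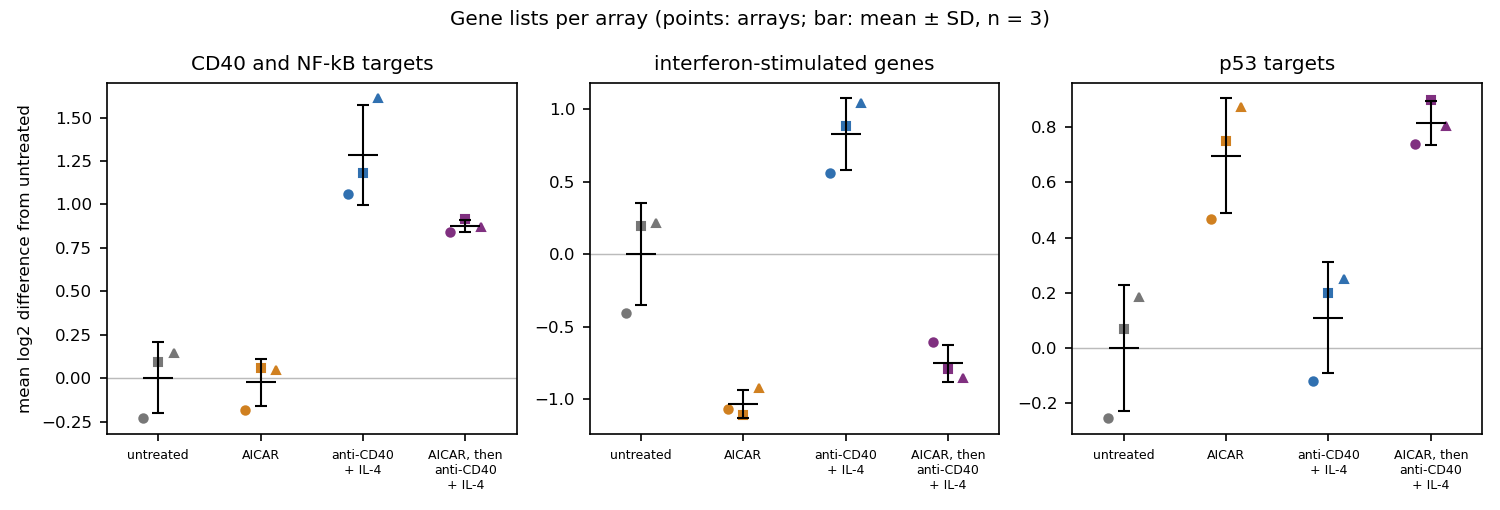
Mean log2 difference from the untreated group over the members of 3 gene lists on each of the 12 arrays, by group; circles, squares and triangles are replicates 1, 2 and 3, and black bars show mean ± SD (n = 3). Interferon-stimulated genes were lower and p53 targets higher in both groups given AICAR (list medians -0.904 and 0.88 against untreated, -1.50 and 0.67 against stimulated).

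In stimulated cells, AICAR pretreatment lowered several of the genes that stimulation had raised. CXCL10 fell from 25.1 ± 6.49 to 0.78 ± 0.287 (mean ± SD, n = 3 and 3; log2 change -4.92 ± 0.35 SE, adjusted p = 5.19e-05) and CXCL11 by 3.54 ± 0.34 (adjusted p = 0.000186). RIGI had a log2 change of -3.59 ± 0.30 (adjusted p = 9.02e-05). IFIT3 and MX2 were not among the probes past the threshold with stimulation, but they fell here as well. IFIT3 fell from 15.6 ± 4.71 to 0.982 ± 0.251 (-3.88 ± 0.38, adjusted p = 0.000198) and MX2 fell 10.5-fold (adjusted p = 0.000162). CCL3, a chemokine of inflammation, fell by 3.02 ± 0.45 (adjusted p = 0.00251) and EBI3 by 2.83 ± 0.33 (adjusted p = 0.00047). CCL17 fell less, from 15.2 ± 6.13 to 5.64 ± 0.92 (-1.40 ± 0.31, adjusted p = 0.0235). Of 38326 probes, 510 rose and 827 fell, for 284 and 613 genes. In all 3517 passed with the replicate block (1553 higher and 1964 lower), among them all 1337. The balance between rises and falls depended on the scaling, with 38.1% of the calls higher here, 53.8% of 825 under median centring and 16.7% of 2258 under the deposited scaling, where the median of all probes lay at 0.102 and -0.241.

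Of 32 interferon-stimulated genes, 16 fell and 0 rose (22 with the block, 22 adjusted over the list alone). Their median was -1.50, at adjusted p = 3.84e-16 (adjusted p = 0.3 with an estimated correlation). IFIT1 fell by 3.10 ± 0.44 (adjusted p = 0.00253). Of 35 CD40 and NF-kB target genes, 5 fell and 0 rose (6 lower and 1 higher with the block, 5 lower adjusted over the list alone). Their median was -0.292, at adjusted p = 0.0189 (adjusted p = 0.932 with an estimated correlation). Besides EBI3, TRAF1 fell by 1.83 ± 0.28 (adjusted p = 0.00344) and LTB, a membrane-anchoring lymphotoxin subunit, by 1.34 ± 0.21 (adjusted p = 0.00373). TRAF3, an adaptor of CD40, fell by 1.09 ± 0.17 (adjusted p = 0.00367), with its other probe opposite in sign. That list call ended under median centring (adjusted p = 0.1, median -0.132), under the deposited scaling (0.15, median -0.475) and without stimulated replicate 3 (0.127), and the median was -0.481 without stimulated replicate 1. Of 24 IL-4 and STAT6 target genes, 4 fell and 0 rose (7 with the block, 4 adjusted over the list alone; list adjusted p = 0.668). Among them were STAT6 (-1.75 ± 0.29, adjusted p = 0.00511) and SOCS1 (-1.65 ± 0.23, adjusted p = 0.00157). FCER2 had a log2 change of -1.04 ± 0.40 (adjusted p = 0.257, 0.00172 with the block) and NFKBIA of -0.53 ± 0.19 (adjusted p = 0.213, 0.0328 with the block).

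Of 37 cytokines and chemokines, 6 fell and 0 rose (7 with the block, 6 adjusted over the list alone), and the list did not pass (adjusted p = 0.322), with a median of 0.0635 and a mean of -0.396. The median was -0.295 under the deposited scaling. Antigen presentation and co-stimulation genes were lower as a list, with 3 of 27 lower and 0 higher (8 lower and 2 higher with the block, 5 lower adjusted over the list alone). Their median was -0.292, at adjusted p = 0.0389 (adjusted p = 0.932 with an estimated correlation). CD58 fell by 1.65 ± 0.20 (adjusted p = 0.000698) and TAP1, a peptide transporter, by 1.90 ± 0.40 (adjusted p = 0.0185). The list call ended under median centring (0.449, median -0.0552), cyclic loess (0.0647) and the deposited scaling (0.468) and with a filter at the 50th percentile (0.0811). It also ended without stimulated replicate 3 (0.281, median -0.17) and AICAR then stimulated replicate 1 (0.19, median -0.154), and the median was -0.533 without stimulated replicate 1. CD83 had a log2 change of 0.65 ± 0.35, past the threshold only with the block (adjusted p = 0.52, 0.0488 with the block). Of 31 B cell identity genes, 4 fell and 0 rose (6 lower and 1 higher with the block, 5 and 1 adjusted over the list alone), and the list passed with the block (adjusted p = 0.066, 0.0394 with the block, and adjusted p = 0.714 with an estimated correlation and the block). SPIB fell by 2.35 ± 0.26 (adjusted p = 0.000369) and PTPN6 by 1.77 ± 0.23 (adjusted p = 0.001).

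Of 27 p53 target genes, 7 rose and 0 fell (13 with the block, 11 adjusted over the list alone). Their median was 0.67, at adjusted p = 6.77e-08 (adjusted p = 0.509 with an estimated correlation). MDM2 rose by 1.95 ± 0.23 (adjusted p = 0.000576), TNFRSF10A by 2.19 ± 0.38 (adjusted p = 0.00648) and ZMAT3 by 1.63 ± 0.22 (adjusted p = 0.00152), and BCL2L11 rose by 1.44 ± 0.24 (adjusted p = 0.00528). Histone genes were higher as a list, with 2 of 28 higher and 1, H2AX, lower (7 and 1 with the block, 6 and 1 adjusted over the list alone). Their median was 0.628, at adjusted p = 0.00156 (adjusted p = 0.932 with an estimated correlation, and adjusted p = 0.0702 with a filter at the 50th percentile). Over the untreated mean, AICAR then stimulated replicates 1, 2 and 3 lay at -0.0329, 0.692 and 0.749. Stimulated replicates 1, 2 and 3 lay at -0.401, -0.216 and 0.119. Replicate 1 was thus the lowest in both groups, and each AICAR array lay above the stimulated array of its number. The median was 0.945 without stimulated replicate 3, 0.419 with that filter and 0.339 under the deposited scaling. The 41 oxidative phosphorylation subunits (median 0.135, adjusted p = 0.0233) and 50 ribosomal proteins (median 0.141, adjusted p = 0.0189) were higher as lists, each with adjusted p = 0.932 with an estimated correlation. They had 0 members past the threshold (3 and 7 with the block, 0 and 0 adjusted over the list alone). Their medians were 0.587 and 0.584 under median centring, 0.118 and 0.0862 under cyclic loess and 0.244 and 0.241 under the deposited scaling. The first of these calls ended without AICAR then stimulated replicate 3 (0.404, median 0.0395) and stimulated replicate 1 (0.125, median 0.0677). The second ended without stimulated replicate 2 (0.286, median 0.0877), AICAR then stimulated replicate 3 (0.223) and AICAR then stimulated replicate 1 (0.104), and under cyclic loess (0.161). The remaining 25 lists did not pass (adjusted p from 0.066 to 0.904). HDAC6 rose by 3.94 ± 0.46 (adjusted p = 0.000503), with its other probe again opposite in sign, GPX1 by 3.07 ± 0.54 (adjusted p = 0.00683) and DIDO1 by 2.74 ± 0.34 (adjusted p = 0.000702), with 1 of 3 other probes opposite in sign. NFYA rose by 2.60 ± 0.33 (adjusted p = 0.000836), RBBP6 by 2.52 ± 0.22 (adjusted p = 0.000108) and LEFTY1, a TGF-beta antagonist, by 2.55 ± 0.35 (adjusted p = 0.00157). VCPIP1 rose by 2.37 ± 0.41 (n = 2 for stimulated, adjusted p = 0.00762, and 1.51 without stimulated replicate 2, where 1 stimulated value was left) and ADAT3, a subunit of a tRNA deaminase, by 2.21 ± 0.21 (adjusted p = 0.000164). CCDC71L (-3.44 ± 0.24, n = 2 for AICAR then stimulated, adjusted p = 5.25e-05), RNF4BP (-3.13 ± 0.24, adjusted p = 5.25e-05) and BTN2A2, a butyrophilin that restrains T cells (-3.07 ± 0.28, adjusted p = 0.000132), fell. So did CPT1B (-1.93 ± 0.23, adjusted p = 0.000525) and POLA2 (-2.12 ± 0.24, adjusted p = 0.000541). TXNIP rose by 1.10 ± 0.18 (adjusted p = 0.00516). CCL22, CISH, IL4R, TNFAIP3, CD40, ICAM1, BCL6, CDKN1A, CCND2, FASN and DDIT4 had log2 changes of 0.26, 0.01, 0.50, -0.20, -0.18, -0.29, -0.07, -0.14, 0.56, -0.54 and -0.04, none past the threshold.

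Of 71 named genes past the threshold, 41 kept their call in every fit that left out 1 array. Without AICAR then stimulated replicate 2 the calls of CCL17 (adjusted p = 0.105), of H3C1 (2.42 ± 0.45, adjusted p = 0.00957, and 0.0518 without it) and of H2BC8 (2.39 ± 0.53, adjusted p = 0.0256, and 0.103 without it) ended. The calls of TAP1 (0.0913) ended without stimulated replicate 3 and of H2AX (0.184) without stimulated replicate 2. The count of probes was 719 and 762 without stimulated replicates 3 and 2 and 757 without AICAR then stimulated replicate 2.

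The AICAR effects without and with stimulation, which share no arrays, were much alike. Of the probes tested, 365 rose in both comparisons, against 6.41 if the calls were independent, 620 fell in both, against 18.8, and 0 moved in opposite directions. The calls share the estimate of each probe's spread, so they would not be independent even without a common effect. Of the 1351 probes called with AICAR alone, 1348 had the same sign in stimulated cells, with a median size of 1.29 alone and 1.19 along the same direction in stimulated cells. Across all probes, which are not independent replicates, the 2 sets of changes had a Pearson correlation of 0.61 and a Spearman correlation of 0.565. MDM2, TNFRSF10A, ZMAT3, GPX1 and HDAC6 rose and IFIT3, MX2, SPIB, CPT1B, POLA2 and CCDC71L fell in both.

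**Figure D3:**
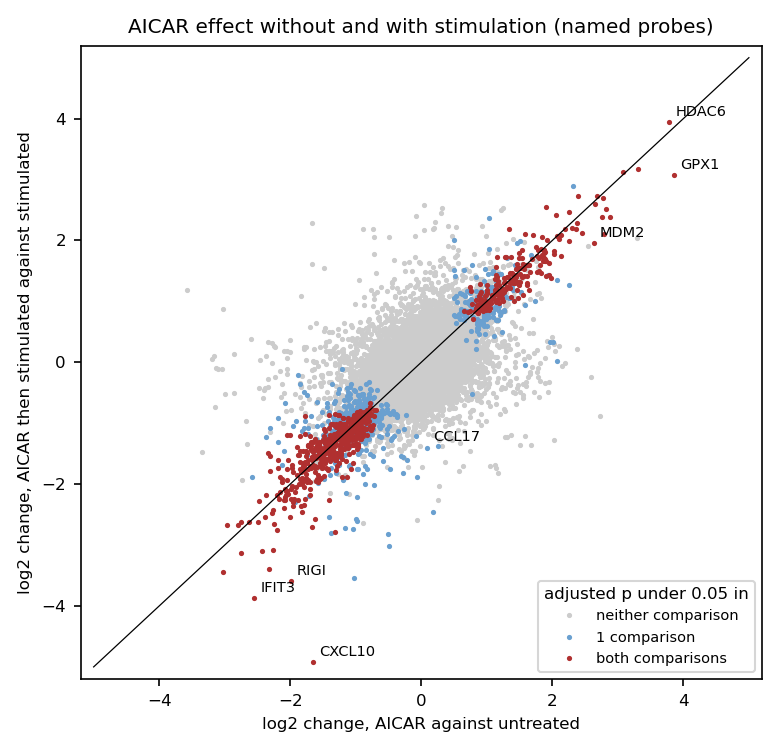
Log2 change with AICAR in unstimulated cells (x axis) against that in stimulated cells (y axis) for the probes with a gene symbol, coloured by the number of comparisons in which they passed an adjusted p of 0.05; the line is equality. HDAC6 (3.78 and 3.94) and GPX1 (3.86 and 3.07) lie high in both, IFIT3 (-2.55 and -3.88) lies low in both, and CXCL10 (-1.65 and -4.92) lies farthest below the line among the labelled genes.

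Stimulation still raised genes in cells given AICAR. CCL17 rose 33.8-fold, from 0.159 ± 0.00399 to 5.64 ± 0.92 (mean ± SD, n = 3 and 3; log2 change 5.08 ± 0.31 SE, adjusted p = 2.37e-05). CD83 rose from 3.47 ± 0.781 to 34.3 ± 5.88 (3.21 ± 0.35, adjusted p = 0.00446), SGK1 by 3.19 ± 0.23 (adjusted p = 7.63e-05). FBLIM1, a filamin-binding adhesion protein, rose by 2.77 ± 0.19 (adjusted p = 5.48e-05), FAS by 2.61 ± 0.23 (adjusted p = 0.000512) and TRAF1 by 2.48 ± 0.28 (adjusted p = 0.00583). In all, 26 probes rose and 0 fell, for 22 genes (1012 at an unadjusted p under 0.05). With the block 70 rose and 3 fell, among them all 26. Of the 26, 18 also rose without AICAR, against 0.0339 if the calls were independent, and all 26 had the same sign there. These calls share the estimate of the spread too.

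Of 35 CD40 and NF-kB target genes, 6 rose and 0 fell (11 with the block, 12 adjusted over the list alone). Their median was 0.571, at adjusted p = 1.04e-28 (adjusted p = 0.0104 with an estimated correlation). NFKBIA rose by 1.57 ± 0.19 (adjusted p = 0.00833) and BCL2A1 by 2.76 ± 0.37 (adjusted p = 0.0139). TNFAIP3 (1.54 ± 0.27, adjusted p = 0.0919, 0.00808 with the block) and CD40 (2.22 ± 0.48, n = 2 after stimulation, adjusted p = 0.366, 0.000661 with the block) passed with the block. TNFAIP3 also passed in the fit of 1 value per gene (0.0465) and without stimulated replicate 1 (0.036). Of 32 immediate early genes, SGK1 alone rose and 0 fell (2 with the block, 3 adjusted over the list alone). Their median was 0.159, or -0.00548 under the deposited scaling, at adjusted p = 8.61e-05 (adjusted p = 0.0234 with an estimated correlation). Of 24 IL-4 and STAT6 target genes, 1 rose (2 with the block, 3 adjusted over the list alone; median 0.197, adjusted p = 8.5e-06, and adjusted p = 0.362 with an estimated correlation). Cytokines and chemokines (3 of 37 higher, 5 with the block, 5 adjusted over the list alone; median 0.0675, or -0.0134 under the deposited scaling) passed at adjusted p = 0.000392 (adjusted p = 0.528 with an estimated correlation). Antigen presentation genes (1 of 27 higher, 4 with the block, 5 adjusted over the list alone; median 0.115) passed at adjusted p = 0.000274 (adjusted p = 0.996 with an estimated correlation). Interferon-stimulated genes were higher as a list by a median of 0.157 (adjusted p = 0.00452, and adjusted p = 0.996 with an estimated correlation) with 0 of 32 members past the threshold (1 adjusted over the list alone). Under median centring, where the median of all probes was 0.217, the medians of the interferon-stimulated and antigen presentation lists were 0.429 and 0.459, and under the deposited scaling 0.077 and 0.107. Those of the CD40, IL-4, cytokine and immediate early lists were 0.879, 0.458, 0.339 and 0.347 under median centring, and the IL-4 median was 0.106 under the deposited scaling. Histone genes were lower by a median of -0.195, or 0.0153 under median centring and -0.337 under the deposited scaling, with 0 of 28 past the threshold (0 adjusted over the list alone; adjusted p = 0.0278, and adjusted p = 0.996 with an estimated correlation). The other 25 lists did not pass (adjusted p from 0.103 to 0.991), although G1 regulators were lower with the block (adjusted p = 0.106, 0.0411 with the block, and adjusted p = 0.587 with an estimated correlation and the block).

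FCER2, CCL22, SOCS1, CISH and IL4R had log2 changes of 0.36, 0.07, 0.59, 0.21 and -0.37, none past the threshold. Of 12 named genes past the threshold, CCL17, CD83, SGK1, FBLIM1, FAS and TRAF1 kept their call in every fit that left out 1 array. Without AICAR then stimulated replicate 2 the calls of EBI3 (2.45 ± 0.33, adjusted p = 0.0139, and 0.114 without it), TNFRSF17, a receptor of plasma cells (1.73 ± 0.23, adjusted p = 0.0139, and 0.114), SWAP70 (1.48 ± 0.22, adjusted p = 0.0302, and 0.189) and NFKBIA (0.061) ended. Without AICAR then stimulated replicate 1 so did those of BCL2A1 (0.112) and KIF26B (3.30 ± 0.50, adjusted p = 0.0354, and 0.241; 1 of its 2 other probes had the opposite sign). The histone call also ended under cyclic loess (0.0888) and the deposited scaling (0.0654). Without AICAR then stimulated replicate 1 the histone list reversed to 0.166 and the interferon-stimulated list no longer passed (0.177). Without AICAR replicate 1 the cytokine (0.0677, median 0.0196) and antigen presentation (0.123, median 0.00044) lists no longer passed. Without AICAR then stimulated replicate 3 the antigen presentation call ended as well (0.0525), and the medians of the 2 lists were -0.0438 for antigen presentation and -0.00881 for cytokines. The histone call ended without AICAR replicates 2 (0.661, median 0.0185) and 3 (0.509, median -0.0775), and its median was -0.474 without AICAR replicate 1. The IL-4 and STAT6 median was 0.387 without AICAR replicate 3, the antigen presentation median 0.273 and the interferon-stimulated median 0.249. The count of probes was 9 without AICAR replicate 3 or AICAR then stimulated replicate 2, 11 and 13 without AICAR then stimulated replicates 1 and 3, and 14 and 17 without AICAR replicates 2 and 1.

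Whether AICAR changed the response to stimulation was tested as an interaction. If AICAR was removed before stimulation, the interaction also holds a difference in exposure, 7 h against 1 h. In single genes the interaction did not pass for any of the 38326 probes (0 in limma, 405 at an unadjusted p under 0.05, smallest adjusted p = 0.873). With the replicate block it passed for 1, CXCL10, singled out after its values were seen. Stimulation raised CXCL10 by 5.18 ± 0.35 without AICAR, against a log2 change of 1.92 ± 0.35 with AICAR (adjusted p = 0.12, 0.00808 with the block), an interaction of -3.27 ± 0.50 (adjusted p = 0.873, 0.0384 with the block). The interactions of CCL17 (-1.49 ± 0.43), NFKBIA (-1.31 ± 0.27), TRAF1 (-0.94 ± 0.40), FCER2 (-0.93 ± 0.57), SOCS1 (-0.61 ± 0.32) and CD83 (-0.27 ± 0.50) did not pass, each at adjusted p = 1. In simulated data with known changes, interactions of 4-fold were recovered in 58.3% and those of 2-fold in 0% of cases. Small ones were therefore not detectable in the fit without a block. Recovery with the block, where 806 probes had an unadjusted p under 0.05 in limma, was not simulated.

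As lists, interferon-stimulated genes had lower interactions, with a median of -0.547 (adjusted p = 5.6e-12, and adjusted p = 0.305 with an estimated correlation), 0 of 32 past the threshold and 2 lower adjusted over the list alone. That median was -0.173 under median centring and -0.299 without untreated replicate 1, and the list test passed in both. CD40 and NF-kB target genes had a median of -0.176, or 0.0701 under median centring and -0.286 under the deposited scaling (adjusted p = 4.3e-08, and adjusted p = 0.305 with an estimated correlation; 0 of 35 past the threshold and 3 lower adjusted over the list alone). Antigen presentation genes had a median of -0.201 with 26 of 27 below 0 (adjusted p = 1.75e-05, and adjusted p = 0.74 with an estimated correlation; 0 past the threshold and 0 adjusted over the list alone), but 0.142 and adjusted p = 0.128 under median centring, where the median of all probes was 0.21, and adjusted p = 0.0721 and a median of -0.0421 without stimulated replicate 3. With 1 array left out, this median reached -0.429 and that of the CD40 and NF-kB target genes -0.295, each without stimulated replicate 1. Cytokines and chemokines had a lower list test at adjusted p = 0.0156 (adjusted p = 0.74 with an estimated correlation) with a mean of -0.281 and a median of 0.0197, which was 0.2 under median centring, -0.0852 without stimulated replicate 1, -0.0365 under cyclic loess and -0.127 under the deposited scaling (0 of 37 past the threshold, 1 with the block and 5 lower adjusted over the list alone). That call ended without AICAR replicate 3 (0.346), stimulated replicate 3 (0.234) and AICAR then stimulated replicate 1 (0.221). IL-4 and STAT6 target genes (lower, median -0.0786, adjusted p = 0.219, 0.0123 with the block) and germinal centre genes (higher, median 0.161, adjusted p = 0.197, 0.00992 with the block) passed with the block. With an estimated correlation and the block these gave adjusted p = 0.589 and adjusted p = 0.559. The IL-4 and STAT6 median was 0.0318 under median centring and -0.318 under the deposited scaling. The germinal centre median was 0.421 and 0.0903 under the same 2 scalings.

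The 50 probes that stimulation raised without AICAR also had changes above 0 with AICAR, with a median log2 change of 2.17 without and 1.56 with AICAR, a ratio of 0.718. Data simulated without any interaction gave a mean ratio of 0.975 over 50 simulations, between 0.835 and 1.09. The simulation gave probes outside the 50 no stimulation effect and used noise independent between arrays. It may therefore hold less of the bias from calling probes on the same arrays, so its gap to 0.718 does not measure a loss of response. Of the 50 interactions, 45 lay below 0, with a median of -0.578 against -0.0738 in the simulations, and 0 passed the threshold (1 with the block, CXCL10). When each replicate number in turn was left out of the call and used for the measurement, the ratios were 0.753, 0.797 and 0.508 over 16, 18 and 13 probes. When only the stimulated array was left out they were 0.67, 0.761 and 0.574 over 40, 36 and 22 probes. There the untreated arrays served both the call and the measurement, so these ratios may still be biased downwards. The average of both AICAR effects lowered 19 of the 50 probes and raised 0, with CXCL10 (-3.28), RIGI (-2.79), CCL3 (-1.76) and EBI3 (-1.66) among those lowered.

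**Figure D4:**
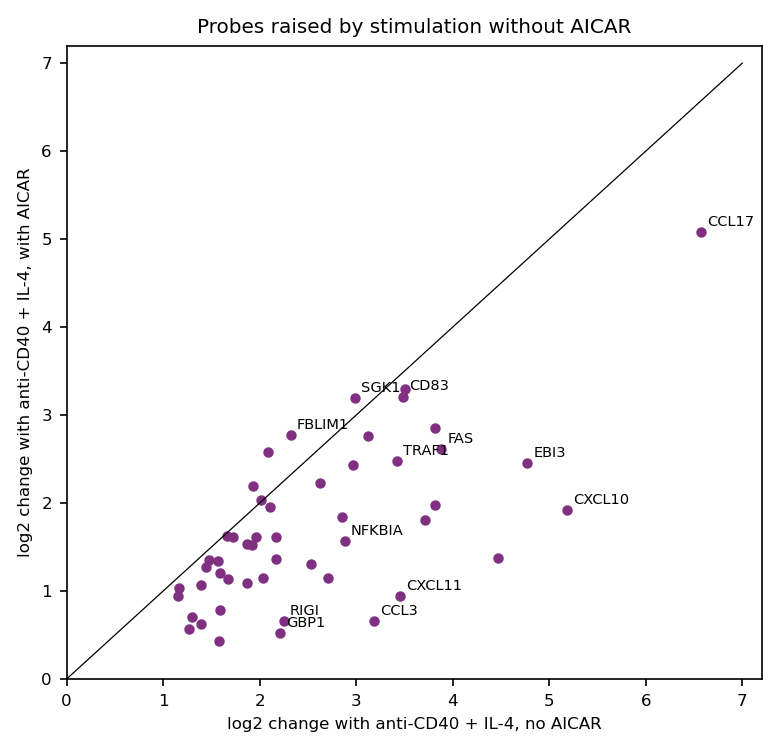
Log2 change with stimulation without AICAR (x axis) and with AICAR (y axis) for the 50 probes that rose without AICAR; the line is equality. Of the 50, 45 lie below the line, with CXCL10 (5.18 and 1.92) and CCL3 (3.18 and 0.66) far below it and CCL17 (6.57 and 5.08) nearer.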

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

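The tests of scaling and of single arrays below were set before their results were seen, and the tests of dim probes and of correlated members after.

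A difference between groups, tested as the interaction of AICAR and stimulation, brought 4 gene lists here, with median interactions of -0.547 for interferon-stimulated genes, -0.176 for CD40 and NF-kB target genes, -0.201 for antigen presentation and co-stimulation genes and 0.0197 for cytokines, chemokines and their receptors. The last median and its list test had opposite signs, with a mean of -0.281.

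Interferon-stimulated genes were lower with AICAR without and with stimulation (medians -0.904 and -1.50), but with an estimated correlation neither list test passed (adjusted p = 0.722 and 0.3). Their median change stayed at -0.794 or below under 3 other scalings in both comparisons and at -0.695 or below whichever array was left out, values that neither the scaling nor a single array accounts for. The median interaction of -0.547 was -0.173 under median centring, where the median of all probes was 0.21, -0.523 under cyclic loess and -0.539 under the deposited scaling, and it ran from -0.702 without stimulated replicate 1 to -0.299 without untreated replicate 1. It was -0.56 among the 27 members with a mean intensity over the 4 groups above 0.258 (25 below 0). In replicates 1, 2 and 3 it was -0.556, -0.299 and -0.803. Because brightness was averaged over all groups, a member may still be dim in the AICAR arrays, so a floor there cannot be excluded. AICAR may lower these genes more strongly in stimulated cells, but the size of the interaction depends on the scaling. With an estimated correlation its adjusted p was 0.305, so correlated members remain a possible account of it, as does a floor in the AICAR arrays. A difference in exposure would also enter it if AICAR was removed before stimulation.

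Target genes of p53 were higher with AICAR without and with stimulation (medians 0.88 and 0.67), but with an estimated correlation neither list test passed (adjusted p = 0.722 and 0.509). Their median change stayed at 0.465 or above under 3 other scalings in both comparisons and at 0.455 or above whichever array was left out, so neither the scaling nor a single array accounts for all of it. Its size did depend on them. It was 0.455 for AICAR alone without untreated replicate 1, and 0.465 in stimulated cells under the deposited scaling. MDM2, TNFRSF10A and ZMAT3 rose in both comparisons, whose changes share no arrays though their calls share the estimate of the spread. AICAR may act on them through p53 or otherwise, which these arrays do not separate.

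Other ways of splitting the 6 arrays of a comparison into 3 and 3 gave at most 0 probes for stimulated against untreated (51 in the real split), 0 for AICAR against untreated (1351), 0 for AICAR then stimulated against stimulated (1337) and 1 for AICAR then stimulated against AICAR (26). In each, 1 of 10 splits, the real split itself, reached the real count, and 10 splits are too few for a share under 0.05. Among the splits that part all 3 same-number pairs, the other 3 gave 0 in every comparison. For the interaction, 100 of 100 labellings, the real one among them, gave at least the real count of 0, with a highest of 2. A real count of 0 is reached by any labelling, so this says nothing about chance.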

How the results depend on the processing

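The deposited scaling and the estimated correlation with the block were added after the data were seen. So were the holding out of all arrays of a replicate number and the average AICAR effect. Processing choices were otherwise fixed before the data were examined. Over the alternatives, values of named genes past the threshold kept their call in 3274 cases and lost it in 503, and lists kept theirs in 606, lost it in 119 and reversed in 1. Where nothing else is said, the cause was not tested.

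Stimulated against untreated (51 probes) gave 166 with the block, 25 with only the groups compared and 22 to 50 with an array left out. AICAR against untreated (1351) gave 744 under median centring, 3459 with the block, 730 with only the groups compared and 647 to 1381 with an array left out. AICAR then stimulated against stimulated (1337) gave 825 under median centring, 2258 under the deposited scaling, 3517 with the block, 801 with only the groups compared and 719 to 1328 with an array left out. AICAR then stimulated against AICAR (26) gave 15 without a variance trend, 73 with the block, 10 with only the groups compared and 9 to 26 with an array left out. The interaction (0) gave 1 with the block and 0 to 2 with an array left out, the highest without AICAR replicate 2. Fits with fewer groups or arrays have fewer samples by construction, and a group left with 2 arrays takes its spread from all groups. They had no block, so variation between replicate numbers stayed in their error. For IFIT1 and POLA2 with AICAR, and VCPIP1 and CCDC71L with AICAR in stimulated cells, which have 2 values in a group, some of these fits leave 1, and their calls there say little.

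Lists past the threshold with the estimated correlation were 3, 0, 0, 2 and 0 for the 5 contrasts in this order, and 4, 0, 0, 2 and 0 with the block added, against 10, 5, 7, 7 and 4. AICAR against untreated had 3 lists with a filter at the 50th percentile and 4 to 8 with an array left out. The interaction had 7 under median centring, 9 under the deposited scaling and 2 to 9 with an array left out. The median of histone genes: AICAR then stimulated against AICAR, ran from -0.474 without AICAR replicate 1 to 0.166 without AICAR then stimulated replicate 1.

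Among the 50 probes raised by stimulation, 1 interaction passed with the block, and the ratio of median effects was 0.583 to 0.749 with an array left out. Of 171 calls of named genes, 51 were lost under median centring. Among printed genes these were CD80, IFIH1 and DDX11-AS1 after stimulation, NFKBIA, SOCS1, CXCL10, NBN, EBF1, TXNIP, CDKN2D and BCL2L11 with AICAR, and CCL17, LTB, TRAF3, TAP1 and H2AX with AICAR in stimulated cells. With only the groups compared 54 were lost. Among printed genes these were KIF26B, DDX11-AS1, DUSP5, CD80, CD58, LMO2, RIGI, IFIH1 and TNFAIP3 after stimulation, and CEP19, NFKBIA, SOCS1, CXCL10, NBN and EBF1 with AICAR. The others were CCL17 and H2AX with AICAR in stimulated cells, and TRAF1, TNFRSF17, SWAP70 and NFKBIA with stimulation after AICAR. Of index genes not past the threshold, 13 values passed under an alternative, 9 of them with the block. SOCS1 (0.0397) and CD40 (0.0488) after stimulation and TNFAIP3 (0.0465) after AICAR then stimulation passed in the fit of 1 value per gene, where their single probes are unchanged and 14425 genes in place of 38326 probes are adjusted over. TNFAIP3 also passed in that comparison without stimulated replicate 1 (0.036). For the printed genes and the list tests the block changed no other call than those given. Without detection flags, changes in probes near background are the least certain.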

Other observations

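The test of brightness and that of dim probes had predictions written before their results were seen, and the test of a condition shared by each replicate number was chosen after.

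Histone genes stood out among families of genes that share the stem of their symbol. Of 84 families with at least 15 genes, only the 49 histone genes passed, with a median log2 change of 0.227 with AICAR alone (4 higher and 0 lower, adjusted p = 0.0051, and adjusted p = 0.986 with an estimated correlation) and of 0.292 with AICAR in stimulated cells (4 higher and 1 lower, adjusted p = 0.000786, and adjusted p = 0.979 with an estimated correlation).

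Probes without a single gene symbol, which were not named, leaned less towards falls than named ones. With AICAR alone, 202 unnamed probes were higher and 220 lower, so that 47.9% were higher, against 280 and 649 named probes, or 30.1%. In stimulated cells 53.4% of the unnamed and 31.6% of the named were higher. Within classes of brightness the odds ratio was still 2.23 (95% interval 1.74 to 2.86) and 2.36 (1.84 to 3.03), so brightness at the resolution of these classes does not account for it. The intervals treat the probes as independent, which they are not, and may be too narrow. Other scalings, under which the share of higher calls moved, were not tried here. No biological explanation was tested.

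Arrays with the same replicate number deviated from their group means together. The replicate term passed the threshold for 8627 of 38326 probes. The exact p of 0.00463 says that the deviations go with the number, but not what the arrays of a number share, which the labels do not give. The mean same-number correlation was 0.517 among the 9582 brightest probes, which noise in dim probes does not account for.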
